A study of Mus musculus with 48 samples.

How the data were processed

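Per the labels' protocols, frozen liver was powdered, RNA was isolated with a column kit, and libraries were made with Lexogen QuantSeq and sequenced with 50-base forward reads. The deposited count table holds counts for 14251 genes in 48 libraries, and per the submitters' processing notes the genome build was GRCm38 and the tools were R 3.6 and DESeq2 1.24.0. The aligner, the counting program, the annotation release and the strand setting are not given in the sources used here. The smallest total of a gene over all libraries was 144 counts, a mean of 3 per library. No step that removed genes with fewer counts is stated. The second deposited table holds normalized signal values, which the authors made with DESeq2, named in the submitters' notes. Its values equal the counts divided by 1 factor per library (largest relative deviation 5.3e-15), and that factor equals the median-of-ratios size factor (largest relative deviation 4.4e-16). It was used only for that check and for gene symbols.

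Symbols came from the normalized table for 12491 gene IDs and from the GENCODE M21 annotation for 1728 more, and 32 IDs had none. Coordinates are those of GENCODE M21 on GRCm38. Every per-sample column was mapped to a labelled sample, with 0 left over. Reads of near-identical copies cannot be told apart where the counting could split them, so values of the Mup, Saa1 and Saa2, Cyp2c, Cyp3a, Cyp4a, Gstm, Acot, Sult2a, Try4 and Try5 and Hba genes are uncertain. The labels give no batch, cage or day, so no such term could be fitted.

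The groups, the tests, the gene lists, the rule for the genes to name and a first set of other settings were chosen before the data were examined. Counts were computed with R 4.3.3. Genes were kept with filterByExpr (minimum count 10, minimum total count 15), which left 12688, and libraries were scaled with TMM factors. All 48 libraries entered 1 fit with a mean per group in edgeR 4.0.16, and each contrast was tested with its quasi-likelihood test. The contrast of the diabetic labels was fitted to the 14 corticosterone control-diet libraries alone, with 12003 genes. Values of p were adjusted over all genes tested by the method of Benjamini and Hochberg, and genes at an adjusted p of at most 0.05 are called changed, higher or lower. CPM are counts scaled to the TMM-adjusted library size. The direction counts give the libraries of the treated group, or of the atglistatin group, that lie on the called side of the mean CPM of the group they are compared with.

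The preset rule named, for each contrast, the 12 highest and the 12 lowest log2 fold changes (8 and 8 for the interaction) among called genes with a symbol and a mean of at least 5 CPM. It also allowed up to 4 members of each gene list with the smallest p, and preset genes of lipid, glucose and steroid metabolism whatever their values. Of the list members and preset genes it allowed, a part is named in the text. Some genes followed are not reported here. There were 39 lists, of which 38 had measured members in the contrast of the diabetic labels. Lists were tested with camera in limma 3.58.1 on log2 CPM with a preset correlation between genes of 0.01 and again with an estimated correlation, and adjusted over the lists of a contrast. Calls of list members are given over all genes and adjusted over the list alone. Glucose and insulin were compared by 2-sided permutation tests of the difference in means with 100000 resamples, or exactly where a side had fewer than 10 values, adjusted over the 9 comparisons.

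Other settings were RLE size factors, DESeq2 1.42.0, limma voom with sample weights, no filter on low counts, the compared groups alone, and the samples without those labelled diabetic. Chosen only after the data were seen were fits without the 6 libraries with Cpa1 above 20 CPM, without corticosterone atglistatin replicate 41, without each library in turn (for the diabetic labels this was chosen before), with a clock index or a small RNA index (mean log2 CPM of 25 small RNA genes) as a covariate, and with robust estimation.

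The edgeR test was first run on simulated counts with changed genes of known fold. For corticosterone on the control diet (12556 genes) it recovered 67.2% of genes changed 1.5-fold and 98.5% of those changed 4-fold. These shares were 67.2% and 98.5% on the atglistatin diet (12538 genes), 65.7% and 97% for atglistatin under vehicle (12570 genes) and 88.1% and 100% for atglistatin under corticosterone (12549 genes). They were 50.7% and 90.9% for the interaction (12542 genes) and 32.8% and 86.4% for the diabetic labels (11876 genes), where 76.1% of genes changed 2-fold were recovered. False calls made up 3.4%, 7.5%, 5.2%, 4.2%, 8.9% and 3% of the calls of these contrasts in the same order.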

Results

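Liver RNA of 48 male C57BL6J mice was profiled by QuantSeq, a library method that reads the 3′ ends of polyadenylated transcripts. The mice had drunk water with corticosterone (100 ug/ml), the main glucocorticoid of rodents, or with ethanol as vehicle for 2 weeks. Within each treatment some mice ate a control diet and others a diet containing atglistatin (571 mg/kg), an inhibitor of adipose triglyceride lipase (ATGL, encoded by Pnpla2), which starts the breakdown of stored triglyceride. The groups held 10 libraries (vehicle, control diet), 10 libraries (vehicle, atglistatin), 14 libraries (corticosterone, control diet) and 14 libraries (corticosterone, atglistatin). Libraries are named here by their group and the number in their title. Total counts per library ran from 7449109 to 17246286 in the vehicle control-diet group, 9318390 to 21086840 in the vehicle atglistatin group, 8417531 to 19548520 in the corticosterone control-diet group and 10832711 to 21175603 in the corticosterone atglistatin group. No pair of libraries within a group agreed within sampling noise, since the smallest chi-square per degree of freedom was 6.70. Each library carries its own glucose and insulin value in the labels, so the spread between libraries is taken as the spread between mice.

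Fed glucose and insulin (no units in the labels) differed between some groups. Mean glucose was 132 ± 10.8 (SD, n = 10) with vehicle on the control diet and 244 ± 79.9 (n = 14) with corticosterone on that diet, a difference of 111 (2-sided permutation test, p = 0.00044, adjusted p = 0.000864). On the atglistatin diet it was 121 ± 16.5 (n = 10) with vehicle and 121 ± 29.9 (n = 14) with corticosterone (permutation adjusted p = 1). Under corticosterone, glucose was lower with atglistatin by a difference of -123 (permutation p = 3e-05, adjusted p = 0.000135), whereas under vehicle the difference of -11.5 did not pass (permutation adjusted p = 0.108). Mean insulin was 2.42 ± 0.705, 1.17 ± 0.514, 31.7 ± 10.6 and 17.94 ± 11.98 in the vehicle control-diet, vehicle atglistatin, corticosterone control-diet and corticosterone atglistatin groups. Insulin rose with corticosterone on the control diet by 29.2 (permutation p = 1e-05, the smallest that 100000 resamples can give, adjusted p = 9e-05), and its lowest corticosterone value of 9.31 lay above the highest vehicle value of 3.46. The rise on the atglistatin diet was 16.8 (permutation adjusted p = 0.000864). Atglistatin lowered insulin by a difference of -1.25 under vehicle (permutation adjusted p = 0.000864) and of -13.7 under corticosterone (permutation adjusted p = 0.00678). The labels call 9 of the 14 corticosterone control-diet mice and 1 of the 14 corticosterone atglistatin mice diabetic. These mice have the highest glucose values of their groups, and leaving them out brought the glucose difference on the control diet to 26.2 (permutation adjusted p = 0.112) by that choice itself. Without these 10, the insulin difference with atglistatin under corticosterone was -9.35 (permutation adjusted p = 0.161).

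**Figure D1:**
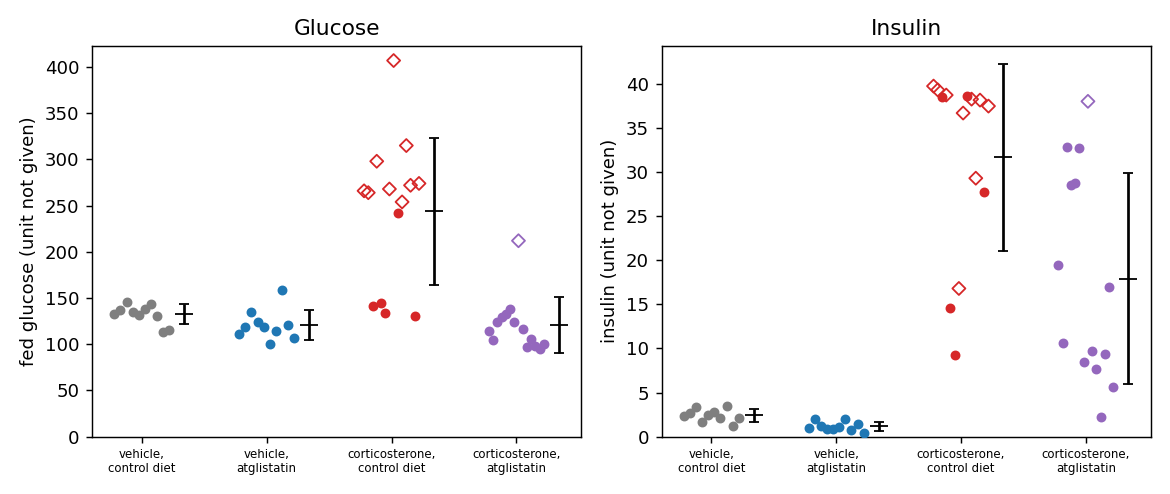
Fed glucose (left) and insulin (right), in the unstated units of the labels, for each of the 48 mice in the 4 groups. Points are mice in the order of their title numbers, open diamonds are mice labelled diabetic, and bars are mean ± SD. Glucose averaged 244 in the corticosterone control-diet group and 121 in the corticosterone atglistatin group.

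On the control diet, corticosterone raised most of the listed glucocorticoid receptor targets and lowered most listed genes of lymphocytes, macrophages and cholesterol synthesis. Of these 4 lists, that of lymphocytes alone also passed camera with an estimated correlation. Fkbp5 (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527, GRCm38), a co-chaperone of the glucocorticoid receptor, rose from 9.603 ± 3.81 CPM (SD, n = 10) to 310.5 ± 91.01 CPM (n = 14), which is 32.5-fold (log2 fold change 5.02 ± 0.27, adjusted p = 3.15e-20). Further values in parentheses are log2 fold changes ± SE. Sult1e1 (ENSMUSG00000029272, chromosome 5, 87575969 to 87591594), an estrogen sulfotransferase, rose from 0.113 ± 0.132 CPM to 109 ± 109.6 CPM (9.76 ± 1.16, adjusted p = 1.3e-09). H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419), a chain of major histocompatibility complex class II, fell from 48.3 ± 17.99 CPM to 3.41 ± 1.06 CPM, which is 14.2-fold (-3.83 ± 0.24, adjusted p = 4.03e-18). Of 12688 genes tested with edgeR's quasi-likelihood test, 5606 passed, 2858 higher and 2748 lower, and 384 of the higher and 759 of the lower ones changed at least 2-fold.

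The glucocorticoid receptor, Nr3c1, fell slightly (-0.42 ± 0.07, adjusted p = 1.42e-06). In the list of its targets, 15 of 20 measured members rose, 1 fell and 4 did not pass, 15 and 2 adjusted over the list alone (median 1.5, camera adjusted p = 9.1e-09, adjusted p = 0.106 with an estimated correlation). Beside Fkbp5 these included Lcn2 (4.87 ± 0.68), the cell cycle inhibitor gene Cdkn1a (4.15 ± 0.29) and Tsc22d3 (1.33 ± 0.24, adjusted p = 7.39e-06). Among genes averaging at least 5 CPM, the 12 with the highest fold changes also included the drug-metabolising Cyp2b10 (6.34 ± 0.4), Cyp17a1 (4.21 ± 0.5) and Obp2a (6.81 ± 0.45). Others were Fam107a (6.98 ± 0.55), Myom3 (5.91 ± 0.32), Slc34a2 (4.45 ± 0.51) and Rgs16 (4.38 ± 0.65). The largest adjusted p among those of the 12 named here was 2.23e-07, for Rgs16. Fam107a moved to 8.11 without vehicle control-diet replicate 12. In the CAR and PXR list of drug-metabolising genes, to which Cyp2b10 belongs, 18 of 32 measured members rose, 3 fell and 11 did not pass, 18 and 3 adjusted over the list alone (median 0.53, camera adjusted p = 0.000473, adjusted p = 0.277 with an estimated correlation). Sult1e1 and Cyp17a1 are known as genes that are higher in female liver. In the list of such genes, 11 of 17 measured members rose, 3 fell and 3 did not pass, 11 and 3 adjusted over the list alone (median 2.3, camera adjusted p = 0.00166, adjusted p = 0.352 with an estimated correlation). The major urinary protein gene Mup17, one of a family whose near-identical copies share reads, fell (-4.59 ± 0.53). In the male-biased list, 3 of 28 measured members rose, 13 fell and 12 did not pass, 3 and 13 adjusted over the list alone (median -0.58, camera adjusted p = 0.00541, adjusted p = 0.671 with an estimated correlation).

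Transcripts of immune cells were lower in all 14 corticosterone libraries than the mean of the vehicle libraries for every member named here. In the T, NK and B cell list, 0 of 14 measured members rose, 13 fell and 1 did not pass, 0 and 13 adjusted over the list alone (median -2.7, camera adjusted p = 2.65e-12, adjusted p = 0.00446 with an estimated correlation). Its named members were Ptprc, the leukocyte antigen CD45 (-2.39 ± 0.18, adjusted p = 1.24e-15), and H2-Aa (-4.11 ± 0.29), H2-Ab1 and Cd74 (-3.79 ± 0.28), 3 genes of antigen presentation that macrophages also express. H2-Eb1 (-3.92 ± 0.27) of the same complex, the interferon-induced chemokine gene Cxcl9 (-4.05 ± 0.31) and the interferon-induced Ifit1 (-2.88 ± 0.33) fell with them. In the list for Kupffer cells, the resident macrophages of the liver, 2 of 19 measured members rose, 15 fell and 2 did not pass, 2 and 15 adjusted over the list alone (median -1.24, camera adjusted p = 7.78e-09, adjusted p = 0.18 with an estimated correlation). Aif1 (-2.55 ± 0.19, adjusted p = 2.68e-15) and the Kupffer cell lectin gene Clec4f (-1.19 ± 0.12, adjusted p = 2.03e-11) were among those that fell. In the fibrosis and extracellular matrix list, 1 of 18 measured members rose, 12 fell and 5 did not pass, 1 and 13 adjusted over the list alone (median -0.64, camera adjusted p = 0.00122, adjusted p = 0.259 with an estimated correlation). The collagen gene Col3a1 fell (-1.77 ± 0.17, adjusted p = 3.97e-12). The remaining genes among the 12 lowest were the immediate early gene Egr1 (-4.43 ± 0.58), the C-type lectin gene Clec2h (-3.32 ± 0.35), Nrep (-3.06 ± 0.31), the carbonic anhydrase gene Car3 (-2.99 ± 0.28) and the antisense transcript Hectd2os (-3.4 ± 0.32). Reads of Hectd2os cannot be told from those of its partner gene, because the strand setting is not given. The largest adjusted p among the 12 lowest was 1.35e-08, for Egr1.

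Lipid and carbohydrate genes moved in both directions. In the cholesterol synthesis list, 1 of 25 measured members rose, 23 fell and 1 did not pass, 1 and 23 adjusted over the list alone (median -1.41, camera adjusted p = 5.8e-17, adjusted p = 0.106 with an estimated correlation). Sc5d (ENSMUSG00000032018, chromosome 9, 42251595 to 42264256), a sterol desaturase gene, fell from 578 ± 100.3 to 122 ± 24.2 CPM (-2.25 ± 0.11, adjusted p = 9.24e-22). Hmgcs1, which encodes the cytosolic enzyme that makes HMG-CoA, fell from 515 ± 123 to 125 ± 45.7 CPM (-2.04 ± 0.18, adjusted p = 4.41e-13). In the glycolysis and glucose uptake list, 10 of 16 measured members rose, 2 fell and 4 did not pass, 10 and 2 adjusted over the list alone (median 0.56, camera adjusted p = 0.00122, adjusted p = 0.0473 with an estimated correlation). The liver pyruvate kinase gene Pklr (2.06 ± 0.24, adjusted p = 6.84e-10) and the fructose kinase gene Khk (1.44 ± 0.16, adjusted p = 4.1e-10) rose. In the gluconeogenesis list, 7 of 14 measured members rose, 0 fell and 7 did not pass, 7 and 0 adjusted over the list alone (median 0.29, camera adjusted p = 0.00258, adjusted p = 0.277 with an estimated correlation). The glucose-6-phosphate transporter gene Slc37a4 (1.94 ± 0.14, adjusted p = 2.32e-16) rose. Pck1 (0.16 ± 0.25, adjusted p = 0.639, 8 of 14 libraries on that side) and G6pc (0.34 ± 0.23, adjusted p = 0.248, 10 of 14 libraries), which encode the enzymes at either end of the pathway, did not pass. G6pc passed with limma voom (log2 fold change 0.56, adjusted p = 0.0294). The hepatokine gene Fgf21 (4.08 ± 0.68, adjusted p = 2.03e-06, 13 of 14 libraries) and the lipid droplet gene Plin5 (1.99 ± 0.15, adjusted p = 4.41e-15) rose, and the fatty acid desaturase gene Scd1 fell (-1.31 ± 0.25, adjusted p = 3e-05). For every other changed gene named in this comparison, all 14 corticosterone libraries lay on the called side of the vehicle mean. In all, 16 of 39 gene lists passed camera, 8 up and 8 down, and 2 passed with an estimated correlation.

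**Figure D2:**
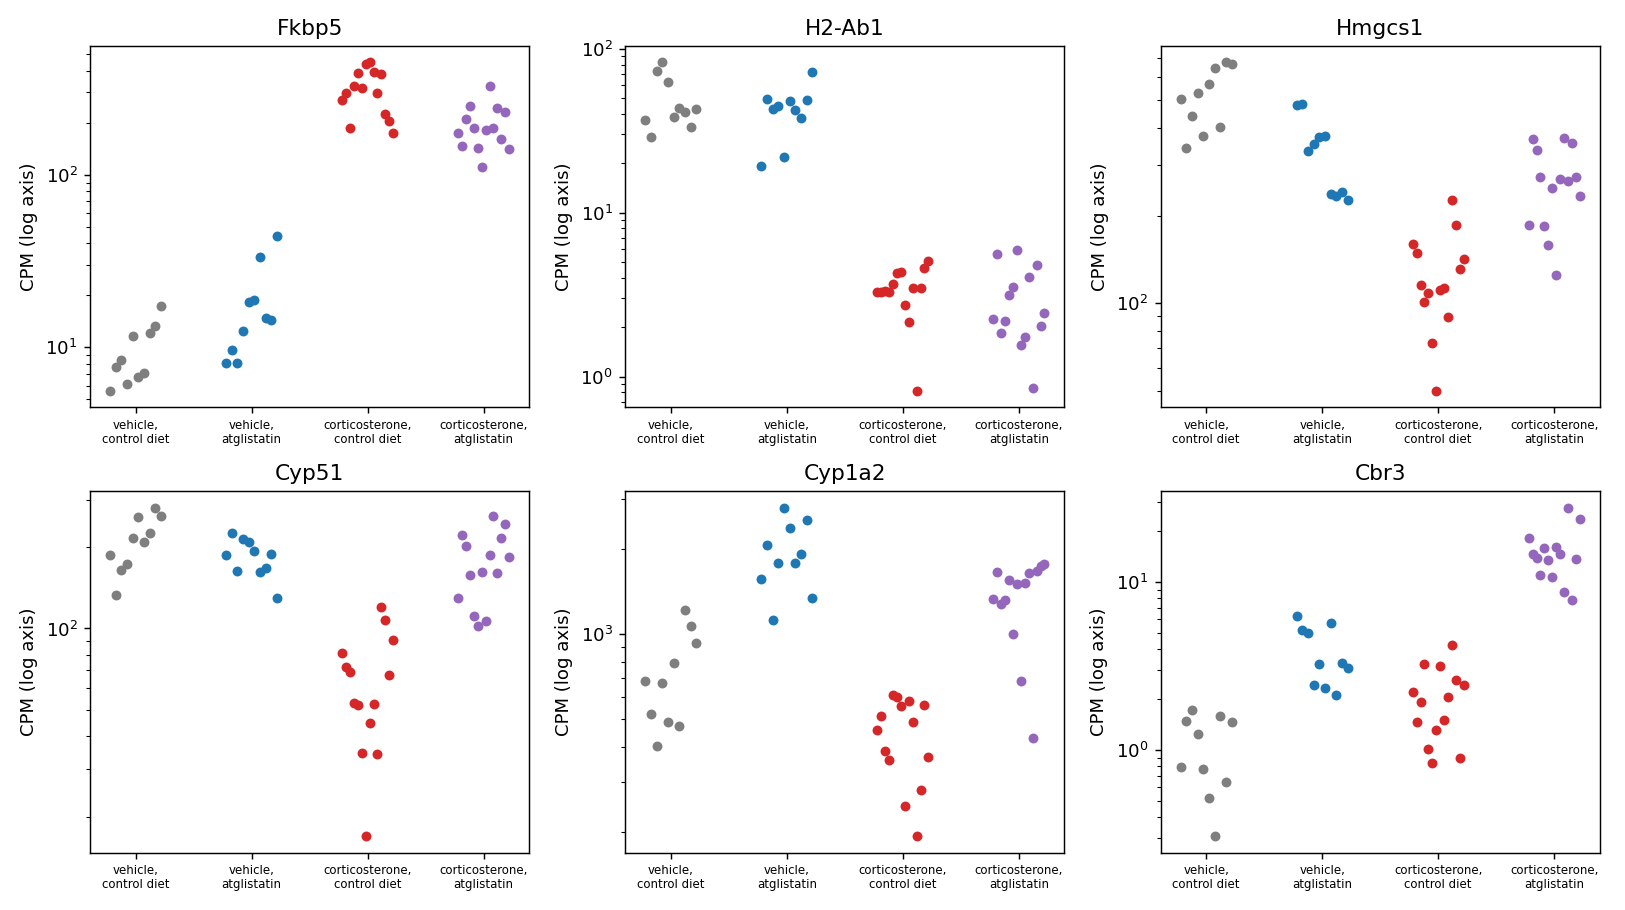
CPM (counts scaled to library size, log axis) of Fkbp5, H2-Ab1, Hmgcs1, Cyp51, Cyp1a2 and Cbr3 in each of the 48 libraries by group; points are libraries. Fkbp5 averaged 9.60 CPM in the vehicle control-diet group and 310.5 CPM in the corticosterone control-diet group, and Cbr3 averaged 2.07 CPM and 15.1 CPM in the corticosterone control-diet and corticosterone atglistatin groups.

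On the atglistatin diet too, corticosterone raised most listed receptor targets and lowered most listed lymphocyte and macrophage genes. Of these 3 lists, that of lymphocytes alone also passed camera with an estimated correlation. Fkbp5 rose from 18.2 ± 11.7 CPM (SD, n = 10) to 192 ± 56.4 CPM (n = 14), which is 10.5-fold (log2 fold change 3.39 ± 0.25, adjusted p = 2.73e-15). H2-Ab1 fell from 42.6 ± 14.8 CPM to 2.99 ± 1.56 CPM (-3.83 ± 0.24, adjusted p = 5.9e-18). The edgeR test called 4652 of 12688 genes, 2411 higher and 2241 lower, with 258 higher and 590 lower at least 2-fold. Of the 5606 genes changed on the control diet, 95.7% had the same sign here. The fold changes correlated across genes (r = 0.807, genes not being independent replicates), and their median ratio, atglistatin diet to control diet, was 0.708 among those genes. Calls shared by both diets were 1805 higher, where independent lists would share 543, and 1761 lower, where they would share 485.

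In the list of glucocorticoid receptor targets, 12 of 20 measured members rose, 1 fell and 7 did not pass, 12 and 1 adjusted over the list alone (median 0.89, camera adjusted p = 4.86e-06, adjusted p = 0.255 with an estimated correlation). Members that rose included Sult1e1 (7.4 ± 1.0), Cdkn1a (4.06 ± 0.29) and Lcn2 (4.22 ± 0.68). The other genes among the 12 highest included Obp2a (6.1 ± 0.43), Fam107a (5.99 ± 0.55), Moxd1 (5.49 ± 1.6, 8 of 14 libraries), Myom3 (5.43 ± 0.31) and Cyp2b10 (4.75 ± 0.37). Scara5 (3.82 ± 0.41), Tff3 (3.62 ± 0.96, 11 of 14 libraries) and Apoa4 (3.6 ± 0.43) were among them too. The adjusted p of these 8 lay between 5.57e-19 for Myom3 and 0.00569 for Moxd1. Without corticosterone atglistatin replicate 41, a library that stood apart from its group, Tff3 was no longer called (1.8, adjusted p = 0.061). Sult1e1 then moved to 5.83, Apoa4 to 2.73, Lcn2 to 2.9 and Fgf21, which rose as on the control diet (2.74 ± 0.56, adjusted p = 0.000116), to 1.83. Without vehicle atglistatin replicate 14, Tff3 moved to 4.31, and without corticosterone atglistatin replicate 48 Moxd1 moved to 4.76. Moxd1 and Tff3 were not called with limma voom (2.60, adjusted p = 0.477, and 1.86, adjusted p = 0.101).

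In the T, NK and B cell list, 0 of 14 measured members rose, 13 fell and 1 did not pass, 0 and 13 adjusted over the list alone (median -2.21, camera adjusted p = 1.46e-15, adjusted p = 0.000678 with an estimated correlation). The immunoglobulin D gene Ighd fell near the lower end of detection, from 0.912 ± 0.247 to 0.0259 ± 0.0489 CPM (-4.69 ± 0.39, adjusted p = 1.13e-13). In the Kupffer cell and macrophage list, 2 of 19 measured members rose, 15 fell and 2 did not pass, 2 and 15 adjusted over the list alone (median -1.13, camera adjusted p = 5.2e-11, adjusted p = 0.134 with an estimated correlation). Clec4f (-1.19 ± 0.12, adjusted p = 4.05e-11) and Timd4 (-1.62 ± 0.17, adjusted p = 9.42e-11) fell. In the list for liver sinusoidal endothelial cells, 0 of 16 measured members rose, 12 fell and 4 did not pass, 0 and 14 adjusted over the list alone (median -0.41, camera adjusted p = 4.25e-06, adjusted p = 0.1 with an estimated correlation). The mannose receptor gene Mrc1 (-0.73 ± 0.09, adjusted p = 8.02e-09) and the VEGF receptor gene Kdr (-0.73 ± 0.09, adjusted p = 9.97e-09) fell. Of the pericentral hepatocyte genes, which are expressed around the central vein, 1 of 16 measured members rose, 8 fell and 7 did not pass, 2 and 9 adjusted over the list alone (median -0.33, camera adjusted p = 0.0186, adjusted p = 0.697 with an estimated correlation). The ornithine aminotransferase gene Oat (-1.87 ± 0.15, adjusted p = 7.04e-14), the Wnt-dependent Lgr5 (-1.1 ± 0.19, adjusted p = 6.42e-06) and Cyp2e1 (-1.05 ± 0.22, adjusted p = 0.000126) were among those that fell. In the cholesterol synthesis list, 0 of 25 measured members rose, 7 fell and 18 did not pass, 0 and 7 adjusted over the list alone (median -0.28, camera adjusted p = 0.0274, adjusted p = 0.934 with an estimated correlation). Sc5d (-1.3 ± 0.11, adjusted p = 2.1e-13) and the sterol sensor gene Insig1 (-0.84 ± 0.18, adjusted p = 0.000186) fell. In the glycolysis list, 8 of 16 measured members rose, 2 fell and 6 did not pass, 8 and 2 adjusted over the list alone (median 0.37, camera adjusted p = 0.00636, adjusted p = 0.1 with an estimated correlation). Pfkfb1 (1.22 ± 0.14, adjusted p = 5.52e-10) rose. Scd1 (-1.66 ± 0.26, adjusted p = 7.89e-07) and the clock output gene Dbp (-1.7 ± 0.36, adjusted p = 0.000204) fell, and Pck1 did not pass (-0.03 ± 0.25, adjusted p = 0.938). With the clock index, the log2 CPM of Dbp minus that of Arntl, as a covariate, Dbp was not called (0.00, adjusted p = 0.998), which that covariate's own construction brings about. Except for Moxd1 and Tff3, and leaving aside the pancreatic genes, all 14 corticosterone libraries lay on the called side for each changed gene named in this comparison. Camera passed 11 of 39 lists, 3 up and 8 down, and 1 with an estimated correlation.

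The 12 lowest fold changes of genes averaging at least 5 CPM were those of Hamp2 (-4.68 ± 0.44, adjusted p = 4.8e-12), a gene of the hepcidin family, and of 11 genes of the exocrine pancreas. These ran from Cpa1 (-6.1 ± 1.53) through Pnlip (-6.07 ± 1.54), Cela3b (-5.98 ± 1.49), Clps (-5.64 ± 1.46), Rnase1 (-5.64 ± 1.52) and Prss2 (-5.59 ± 1.52) to Cpb1 (-5.51 ± 1.5), Ctrb1 (-5.48 ± 1.54) and Ctrl (-5.47 ± 1.4). Try4 (-5.31 ± 1.46) and Try5 (-5.28 ± 1.51) are near-identical copies that share reads. Cpa1 was above 20 CPM in 6 of the 48 libraries, at 998 CPM in vehicle atglistatin replicate 06, 332 CPM in corticosterone control-diet replicate 30, 67.5, 32.6 and 25.6 CPM in vehicle control-diet replicates 09, 10 and 15 and 37.8 CPM in vehicle atglistatin replicate 11. All 9 measured genes of the pancreatic list fell (median log2 fold change -5.59), but its camera adjusted p was 0.281. Without vehicle atglistatin replicate 06, none of the 11 genes was called, with log2 fold changes between -1.93 for Pnlip (adjusted p = 0.278) and -1.42 for Ctrb1 (adjusted p = 0.438), nor were they called with DESeq2 or limma voom. Without the 6 libraries with Cpa1 above 20 CPM, Cpa1 was at 1.83 (adjusted p = 0.104) and Ctrb1 at 2.03 (adjusted p = 0.0828). Without corticosterone atglistatin replicate 23, Cpa1 moved to -6.73, Clps to -6.34, Rnase1 to -6.37, Prss2 to -6.18, Cpb1 to -6.15 and Ctrb1 to -6.21, and without corticosterone atglistatin replicate 47 Cpa1 moved to -6.69 and Pnlip to -6.67. Cela3b, Ctrl, Try4 and Try5 did not reach the count filter without any 1 of corticosterone atglistatin replicates 13, 23 and 47 and corticosterone control-diet replicate 30. Hamp2 moved to -3.99 without vehicle atglistatin replicate 14.

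In vehicle-treated mice, atglistatin raised some genes of drug metabolism and of the aryl hydrocarbon receptor (AHR) response. Clock genes differed between the groups, for which the labels give no hour of collection. Cyp1a2 (ENSMUSG00000032310, chromosome 9, 57676937 to 57683703), a cytochrome P450 gene induced through AHR, rose from 726 ± 274 CPM (SD, n = 10) to 1928 ± 528 CPM (n = 10), which is 2.66-fold (log2 fold change 1.41 ± 0.22, adjusted p = 6.52e-05). Cbr3 (ENSMUSG00000022947, chromosome 16, 93683215 to 93690990), a carbonyl reductase gene, rose 3.61-fold from 1.06 ± 0.507 to 3.85 ± 1.52 CPM (1.85 ± 0.29, adjusted p = 6.64e-05). Dbp (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203), a clock output transcription factor gene, rose 7.75-fold from 5.402 ± 3.36 to 41.6 ± 36.96 CPM (2.95 ± 0.44, adjusted p = 3.04e-05). The edgeR test called 397 of 12688 genes, 186 higher and 211 lower, with 38 and 54 at least 2-fold. Pnpla2, which encodes the enzyme that atglistatin inhibits (0.34 ± 0.16, adjusted p = 0.261, 9 of 10 libraries), did not pass. Nor did G0s2, which encodes a protein inhibitor of it (-0.06 ± 0.33, adjusted p = 0.957, 7 of 10 libraries).

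In the CAR and PXR list, 8 of 32 measured members rose, 0 fell and 24 did not pass, 20 and 0 adjusted over the list alone (median 0.5, camera adjusted p = 2.47e-16, adjusted p = 0.0114 with an estimated correlation). These included the glutathione transferase genes Gstm1 (0.95 ± 0.11, adjusted p = 1.27e-07) and Gstm3 (1.61 ± 0.3, adjusted p = 0.000551), which share reads with others of their family, and Nr1i3 (1.01 ± 0.17, adjusted p = 0.000154), which encodes the receptor CAR. In the AHR list, 3 of 5 measured members rose, 0 fell and 2 did not pass, 4 and 0 adjusted over the list alone (median 1.04, camera adjusted p = 3.25e-08, adjusted p = 4.9e-05 with an estimated correlation). Cyp1a2, Cyp1a1 (2.11 ± 0.36, adjusted p = 0.000244) and Nqo1 (1.04 ± 0.19, adjusted p = 0.000551) rose. In the list of targets of NRF2, the transcription factor of the antioxidant response, 4 of 17 measured members rose, 0 fell and 13 did not pass, 9 and 0 adjusted over the list alone (median 0.28, camera adjusted p = 8.87e-06, adjusted p = 0.172 with an estimated correlation). Cyp2a5, a pericentral cytochrome P450 gene, rose as well (1.86 ± 0.24, adjusted p = 1.63e-06). Among targets of the fatty acid receptor PPARα, 4 of 36 measured members rose, 0 fell and 32 did not pass, 5 and 0 adjusted over the list alone (median 0.2, camera adjusted p = 2.45e-06, adjusted p = 0.337 with an estimated correlation). Cyp4a14 (1.89 ± 0.39, adjusted p = 0.00194), Cyp4a10 (1.29 ± 0.31, adjusted p = 0.0105) and the thioesterase gene Acot3 (2.05 ± 0.52, adjusted p = 0.0148), all of families with similar copies, rose. In the female-biased list, 4 of 17 measured members rose, 0 fell and 13 did not pass, 8 and 0 adjusted over the list alone (median 0.8, camera adjusted p = 7.37e-05, adjusted p = 0.262 with an estimated correlation). Fmo2 rose (1.36 ± 0.35, adjusted p = 0.0173). The lysolipid transporter gene Mfsd2a rose too (1.48 ± 0.39, adjusted p = 0.0184, 9 of 10 libraries). Fkbp5 also rose (0.94 ± 0.25, adjusted p = 0.0207, 8 of 10 libraries). Without vehicle atglistatin replicate 14, Acot3 (1.72, adjusted p = 0.0533), Fmo2 (0.94, adjusted p = 0.106), Mfsd2a (1.28, adjusted p = 0.0572) and Fkbp5 (0.7, adjusted p = 0.0943) were not called. Without vehicle atglistatin replicate 11, Mfsd2a (1.25, adjusted p = 0.0707) and Fkbp5 (0.8, adjusted p = 0.074) were not called, and Mfsd2a was at 2.09 without vehicle control-diet replicate 12.

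In the circadian clock list, 7 of 20 measured members rose, 3 fell and 10 did not pass, 13 and 4 adjusted over the list alone (median 0.59, camera adjusted p = 6.3e-05, adjusted p = 0.0485 with an estimated correlation). Beside Dbp, the deubiquitinase gene Usp2 (2.23 ± 0.41, adjusted p = 0.000592), Per3 (2.17 ± 0.37, adjusted p = 0.000244), Tef (1.14 ± 0.2, adjusted p = 0.000408) and Bhlhe41 (2.53 ± 0.44, adjusted p = 0.000293) rose, each in 10 of 10 libraries. The clock index was -0.866 ± 1.74 (SD, n = 10) in the vehicle control-diet group, 2.98 ± 2.11 (n = 10) in the vehicle atglistatin group, -1.88 ± 1.16 (n = 14) in the corticosterone control-diet group and 0.571 ± 1.27 (n = 14) in the corticosterone atglistatin group. With that index as a covariate, a setting chosen after the data were seen, 15 genes passed in place of 397, and 28 of the 36 changed genes followed in this comparison, Dbp, Usp2, Per3, Tef and Bhlhe41 among them, were not called. Cyp1a2, Cyp1a1, Gstm1, Cbr3, Cyp2a5, Mup17, Mup9 and Dnajb1 were called with it.

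**Figure D3:**
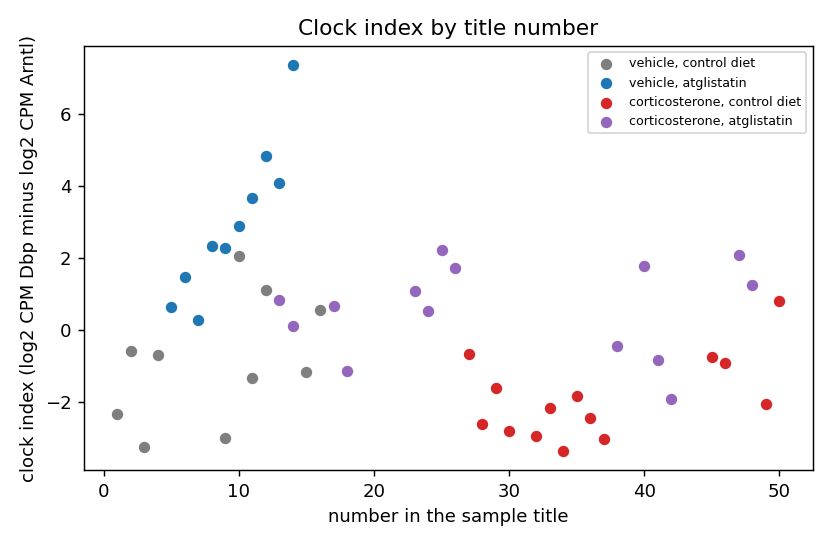
Clock index (vertical axis, log2 CPM of Dbp minus log2 CPM of Arntl) of each of the 48 libraries against the number in its sample title (horizontal axis), with colours for the 4 groups; points are libraries. The index averaged -0.866 in the vehicle control-diet group and 2.98 in the vehicle atglistatin group.

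Some male-biased and some immediate early genes were lower with atglistatin, and neither list passed camera with an estimated correlation. In the male-biased list, 0 of 28 measured members rose, 6 fell and 22 did not pass, 1 and 15 adjusted over the list alone (median -0.79, camera adjusted p = 1.14e-12, adjusted p = 0.216 with an estimated correlation). The serpin gene Serpina1e (-1.75 ± 0.36, adjusted p = 0.00207) and Selenbp2 (-2.35 ± 0.63, adjusted p = 0.0235) fell. Of the major urinary protein genes, whose near-identical copies share reads, Mup17 (-2.85 ± 0.57, adjusted p = 0.00141), Mup9 (-1.96 ± 0.42, adjusted p = 0.00308) and Mup18 (-1.27 ± 0.37, adjusted p = 0.0425) fell. In the immediate early list, 0 of 14 measured members rose, 2 fell and 12 did not pass, 0 and 7 adjusted over the list alone (median -0.48, camera adjusted p = 0.00105, adjusted p = 0.224 with an estimated correlation). Nr4a1 (-2.23 ± 0.51, adjusted p = 0.00586) and Btg2 (-1.18 ± 0.34, adjusted p = 0.0442) fell. In the list of lipogenesis genes, 0 of 21 measured members rose, 2 fell and 19 did not pass, 0 and 3 adjusted over the list alone (median -0.19, camera adjusted p = 0.00353, adjusted p = 0.337 with an estimated correlation). The ATP citrate lyase gene Acly (-0.76 ± 0.17, adjusted p = 0.00671) and the carboxylase gene Acacb (-0.75 ± 0.17, adjusted p = 0.00666) fell. The other genes among the 12 lowest included Moxd1 (-6.39 ± 1.6, adjusted p = 0.0144), Tff3 (-3.54 ± 0.99, adjusted p = 0.0328) and the fatty acid binding protein gene Fabp5 (-2.12 ± 0.36, adjusted p = 0.000244). The rest were the chaperone gene Dnajb1 (-2.02 ± 0.51, adjusted p = 0.0142), the stress-induced Gadd45g (-1.73 ± 0.45, adjusted p = 0.0171), the choline kinase gene Chka (-1.32 ± 0.3, adjusted p = 0.00625) and Capn8 (-1.29 ± 0.32, adjusted p = 0.014). Except for Fkbp5 and Mfsd2a, and leaving aside Dnajb1, Moxd1 and Tff3, where 1 library weighs on the mean, all 10 atglistatin libraries lay on the called side of the control-diet mean for each changed gene named in this comparison.

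Single vehicle libraries decided several of these calls. Dnajb1 was at a log2 CPM of 9.5 in vehicle control-diet replicate 10, against 3.58 to 5.2 in the other 9 of its group, and turned to 0.24 (adjusted p = 0.608) without it. It was also above 0 with DESeq2 (0.20, adjusted p = 0.653) and limma voom (0.10, adjusted p = 0.875). Without vehicle control-diet replicate 09, Moxd1 (-5.08, adjusted p = 0.0824), Tff3 (-1.61, adjusted p = 0.404) and Selenbp2 (-2.17, adjusted p = 0.0504) were not called. Tff3 was also not called without any 1 of vehicle atglistatin replicates 08 (-3.43), 10 (-3.48), 11 (-3.47), 12 (-3.42) and 13 (-3.52), with adjusted p between 0.0539 and 0.0638, and was at -4.23 without vehicle atglistatin replicate 14. Nr4a1 lost its call without vehicle control-diet replicate 04 (-1.4, adjusted p = 0.0771), Gadd45g without vehicle control-diet replicate 11 (-1.53, adjusted p = 0.0533) and Selenbp2 without vehicle atglistatin replicate 11 (-2.23, adjusted p = 0.0519). Btg2 lost it without any 1 of 14 libraries (-1.21 to -0.90, adjusted p 0.0533 to 0.146) and Mup18 without any 1 of 11 (-1.29 to -1.04, adjusted p 0.0532 to 0.0999). With limma voom, Acot3, Fmo2, Moxd1, Tff3, Gadd45g, Capn8 and Mup18 were not called although 899 genes passed in all, 397 higher and 502 lower, and Tff3 was not called with DESeq2. In the fit of the vehicle groups alone, Nr4a1, Btg2, Fkbp5, Mfsd2a, Dnajb1 and Chka were not called. Without the 6 libraries with Cpa1 above 20 CPM, 207 genes passed, 165 of them among the 397, and Acot3, Btg2, Fkbp5, Mfsd2a, Fmo2, Moxd1, Tff3, Selenbp2, Chka, Capn8 and Mup18 were not called. In all, 15 of 39 lists passed camera, 7 up and 8 down, and 3 with an estimated correlation.

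**Figure D4:**
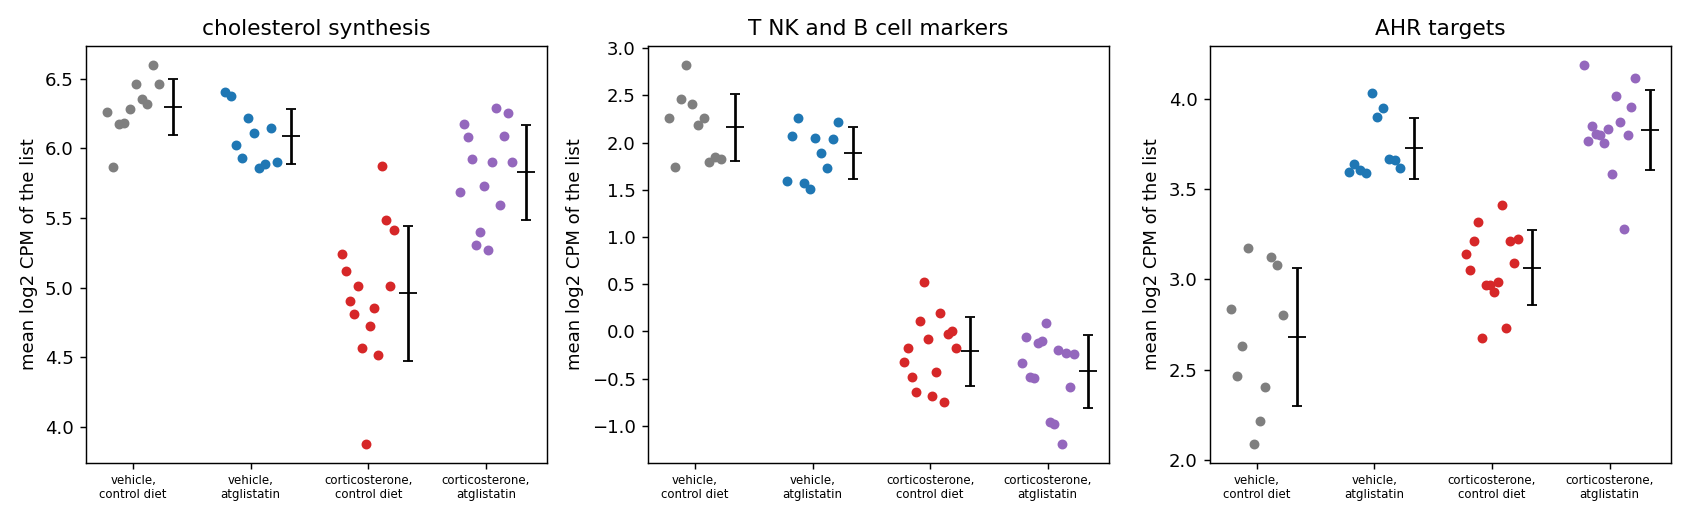
Mean log2 CPM per library of the measured members of the cholesterol synthesis, T NK and B cell and AHR target lists, by group; points are libraries and bars are mean ± SD. The T, NK and B cell list had a median log2 fold change of -2.70 with corticosterone on the control diet, and the cholesterol synthesis list one of 0.85 with atglistatin under corticosterone.

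The next comparison asked what atglistatin changed in corticosterone-treated mice. Most genes of the cholesterol synthesis list were higher with atglistatin. Some antioxidant and drug metabolism genes were higher, and some acute phase, gluconeogenesis and amino acid breakdown genes lower, in lists that did not pass camera with an estimated correlation. Cyp51 (ENSMUSG00000001467, chromosome 5, 4081145 to 4104746), a lanosterol demethylase gene, rose from 63.97 ± 28.99 CPM (SD, n = 14) to 175 ± 51.03 CPM (n = 14), which is 2.73-fold (log2 fold change 1.45 ± 0.18, adjusted p = 2.93e-08). Cbr3 rose 7.25-fold from 2.07 ± 0.992 to 15.1 ± 5.399 CPM (2.86 ± 0.21, adjusted p = 1.38e-14). Slc34a2 (ENSMUSG00000029188, chromosome 5, 53038081 to 53071664) fell from 16.9 ± 17.2 to 0.913 ± 0.709 CPM (-4.15 ± 0.42, adjusted p = 1.66e-10). The edgeR test called 1479 of 12688 genes, 658 higher and 821 lower, with 74 and 122 at least 2-fold. Pnpla2 did not pass (-0.01 ± 0.13, adjusted p = 0.987, 11 of 14 libraries).

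In the cholesterol synthesis list, 20 of 25 measured members rose, 0 fell and 5 did not pass, 21 and 0 adjusted over the list alone (median 0.85, camera adjusted p = 1.13e-28, adjusted p = 0.0426 with an estimated correlation). With Cyp51, the squalene epoxidase gene Sqle (1.5 ± 0.23, adjusted p = 5.63e-06) and the squalene synthase gene Fdft1 (ENSMUSG00000021273, chromosome 14, 63145150 to 63179578, 1.33 ± 0.13, adjusted p = 5.69e-11) rose. In the NRF2 list, 7 of 17 measured members rose, 0 fell and 10 did not pass, 9 and 1 adjusted over the list alone (median 0.31, camera adjusted p = 2.75e-08, adjusted p = 0.0558 with an estimated correlation). Gclc, which encodes the catalytic subunit of the first enzyme of glutathione synthesis (1.09 ± 0.11, adjusted p = 5.55e-11), and the glutathione transferase gene Gsta1 (1.92 ± 0.36, adjusted p = 0.000159) rose. In the AHR list, 3 of 5 measured members rose, 1 fell and 1 did not pass, 3 and 1 adjusted over the list alone (median 0.93, camera adjusted p = 0.00174, adjusted p = 0.0426 with an estimated correlation). Cyp1a2 rose 3.08-fold (1.62 ± 0.18, adjusted p = 4.34e-09, 13 of 14 libraries). In the CAR and PXR list, 9 of 32 measured members rose, 3 fell and 20 did not pass, 9 and 5 adjusted over the list alone (median 0.05, camera adjusted p = 0.00669, adjusted p = 0.39 with an estimated correlation). Gstm3 (1.88 ± 0.25, adjusted p = 2.49e-07) rose. The 12 highest also held Cyp2a5 (1.51 ± 0.2, adjusted p = 1.94e-07), the cyclin gene Ccng1 (1.55 ± 0.12, adjusted p = 2.03e-14), the mannose-binding lectin gene Mbl2 (1.4 ± 0.12, adjusted p = 2.92e-13) and Dbp (1.89 ± 0.38, adjusted p = 0.000366, 13 of 14 libraries). The small nucleolar RNA gene Snora30 (1.49 ± 0.32, adjusted p = 0.000955) and the cyclin gene Ccnd1 (1.92 ± 0.49, adjusted p = 0.00583, 4 of 14 libraries) were among the 12 too. Ccnd1 rested on corticosterone atglistatin replicate 41, without which it was at -0.18 (adjusted p = 0.442). It lay below 0 with DESeq2 (-0.05, adjusted p = 0.905) and limma voom (-0.01, adjusted p = 0.993). The gene of the receptor PPARα, Ppara, rose (0.58 ± 0.12, adjusted p = 0.000794).

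In the acute phase and inflammation list, 0 of 32 measured members rose, 11 fell and 21 did not pass, 1 and 16 adjusted over the list alone (median -0.29, camera adjusted p = 1.78e-08, adjusted p = 0.208 with an estimated correlation). The serum amyloid genes Saa1 (-3.87 ± 0.68, adjusted p = 5.43e-05) and Saa2 (-3.36 ± 0.67, adjusted p = 0.000372), which share reads, fell. So did the orosomucoid genes Orm3 (ENSMUSG00000028359, chromosome 4, 63356162 to 63359511, -2.61 ± 0.29, adjusted p = 2.24e-09) and Orm2 (-2.19 ± 0.34, adjusted p = 5.29e-06). Without corticosterone atglistatin replicate 41, Saa1 was at -4.78 and Saa2 at -4.23, and without corticosterone control-diet replicate 45 Saa2 was at -2.51. In the gluconeogenesis list, 0 of 14 measured members rose, 7 fell and 7 did not pass, 0 and 7 adjusted over the list alone (median -0.27, camera adjusted p = 0.00552, adjusted p = 0.39 with an estimated correlation). G6pc (-1.05 ± 0.21, adjusted p = 0.000429), the alanine transaminase gene Gpt2 (-0.45 ± 0.08, adjusted p = 0.000132) and the pyruvate carboxylase gene Pcx (-0.5 ± 0.1, adjusted p = 0.000586) fell. Pck1 did not pass (0.24 ± 0.23, adjusted p = 0.583). In the amino acid catabolism list, 0 of 43 measured members rose, 11 fell and 32 did not pass, 0 and 14 adjusted over the list alone (median -0.23, camera adjusted p = 2.75e-08, adjusted p = 0.39 with an estimated correlation). Oat (-1.13 ± 0.14, adjusted p = 5.1e-08) fell. Rhbg, an ammonium transporter gene expressed with Oat in pericentral hepatocytes, also fell (-1.62 ± 0.19, adjusted p = 1.46e-08). In the lipogenesis list, 2 of 21 measured members rose, 7 fell and 12 did not pass, 2 and 8 adjusted over the list alone (median -0.3, camera adjusted p = 0.0156, adjusted p = 0.39 with an estimated correlation). The carboxylase gene Acaca (-0.87 ± 0.15), Thrsp (-0.97 ± 0.22, adjusted p = 0.00172) and the fatty acid synthase gene Fasn (-0.7 ± 0.17, adjusted p = 0.00474, 13 of 14 libraries) fell. The fatty acid translocase gene Cd36 fell (-0.63 ± 0.2, adjusted p = 0.0325, 12 of 14 libraries). It lost its call without any 1 of 7 libraries, namely corticosterone control-diet replicate 30 (-0.52), 35 (-0.55) and 45 (-0.56) and corticosterone atglistatin replicate 17 (-0.59), 18 (-0.59), 47 (-0.6) and 48 (-0.59). The adjusted p lay between 0.0502 and 0.0771. The call was also lost in the fit of the corticosterone groups alone (adjusted p = 0.0658). In the list of glucocorticoid receptor targets, 0 of 20 measured members rose, 3 fell and 17 did not pass, 0 and 6 adjusted over the list alone (median -0.48, camera adjusted p = 0.000602, adjusted p = 0.39 with an estimated correlation). Fkbp5 (-0.69 ± 0.2, adjusted p = 0.0141, 13 of 14 libraries) and the metallothionein gene Mt2 (-1.6 ± 0.44, adjusted p = 0.0111) fell.

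The remaining 9 of the 12 lowest were the pancreatic genes Try5 (-5.03 ± 1.46), Cpb1 (-4.3 ± 1.42), Prss2 (-4.23 ± 1.42), Cela3b (-4.2 ± 1.4), Try4 (-4.19 ± 1.39), Rnase1 (-4.19 ± 1.42), Ctrb1 (-4.15 ± 1.43), Clps (-3.96 ± 1.37) and Ctrl (-3.85 ± 1.32). Their adjusted p ran from 0.017 for Try5 to 0.0496 for Clps. In the pancreatic list, 6 of 9 measured members fell with a median of -4.15 and a mean of -3.86, while camera gave the direction as up (adjusted p = 0.959). Without corticosterone control-diet replicate 30, Cpb1 was at 4.88, Prss2 at 3.73, Rnase1 at 3.56, Ctrb1 at 3.38 and Clps at 3.93, with adjusted p between 0.202 for Ctrb1 and 0.278 for Clps. Cela3b, Try4, Try5 and Ctrl then did not reach the count filter, nor did they without corticosterone atglistatin replicate 13, 23 or 47. Without corticosterone atglistatin replicate 23, Cpb1 was at -4.95, Prss2 at -4.83, Rnase1 at -4.92, Ctrb1 at -4.88 and Clps at -4.66. Other single libraries ended the calls too, and the libraries that did so numbered 11 for Cpb1 and Prss2, 10 for Cela3b and Try4, 13 for Rnase1 and Ctrl, 18 for Ctrb1 and 21 for Clps. All 9 lay above 0 with DESeq2, from 2.39 for Ctrl to 4.83 for Cpb1, and none was called with limma voom.

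Except for Cyp1a2, Dbp, Ccnd1, Fasn, Cd36 and Fkbp5, and leaving aside the pancreatic genes, all 14 atglistatin libraries lay on the called side of the corticosterone control-diet mean for each changed gene named in this comparison. Camera passed 13 of 39 lists, 4 up and 9 down, and 2 with an estimated correlation. Among the 397 genes called with atglistatin under vehicle, 87.9% had the same sign under corticosterone. The calls shared were 79 higher and 89 lower, where independent lists would share 9.65 and 13.6. Without the samples labelled diabetic, 609 genes passed and G6pc, Fasn, Cd36, Fkbp5, Mt2, Ccnd1 and Snora30 were not called. With the clock index as a covariate, chosen after the data were seen, 793 genes passed and Fasn, Cd36, Ppara, Dbp, Snora30 and the 9 pancreatic genes were not called.

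The interaction is the corticosterone log2 fold change on the atglistatin diet minus that on the control diet. The corticosterone fold changes of cholesterol synthesis genes were less negative on the atglistatin diet, and that of Fkbp5 was lower. Hmgcs1 (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260) went from 515 ± 123 to 125 ± 45.7 CPM with corticosterone on the control diet (n = 10 and 14). On the atglistatin diet it went from 334 ± 99.3 to 260.2 ± 78.2 CPM (n = 10 and 14), an interaction of 1.68 ± 0.26 (adjusted p = 4.91e-05). The interaction of Fkbp5 was -1.63 ± 0.32 (adjusted p = 0.00175). The edgeR test called 181 of 12688 genes, 89 above 0 and 92 below 0. In the cholesterol synthesis list, 17 of 25 measured members were called above 0, none below, and 21 adjusted over the list alone (median 1.13, camera adjusted p = 2.06e-41, adjusted p = 0.012 with an estimated correlation). Besides Hmgcs1 they included Sqle (1.69 ± 0.35), Cyp51 (1.64 ± 0.27), Msmo1 (1.57 ± 0.28), Fdft1 (1.48 ± 0.2) and Lss (1.47 ± 0.22), with adjusted p between 2.83e-06 for Fdft1 and 0.00452 for Sqle.

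Genes called below 0 included Orm3, which with corticosterone averaged 30.2 ± 17.1 CPM on the control diet and 4.88 ± 1.99 CPM on the atglistatin diet (interaction -3.01 ± 0.48, adjusted p = 8.15e-05). Below 0 too were Cyp4a10 (-1.95 ± 0.41, adjusted p = 0.00454) and Cyp4a14 (-1.83 ± 0.49, adjusted p = 0.0432), Slc37a4 (-0.8 ± 0.18, adjusted p = 0.0116) and Hamp2 (-2.4 ± 0.58, adjusted p = 0.0213). Rgs16 (-2.96 ± 0.79, adjusted p = 0.0414), Cyp2b10 (-1.6 ± 0.44, adjusted p = 0.0483) and Try5 (-7.61 ± 2.1, adjusted p = 0.0496) were below 0 as well. In the pericentral list, 4 of 16 measured members were called below 0 and 5 adjusted over the list alone (camera adjusted p = 0.000115, adjusted p = 0.407 with an estimated correlation). They included Oat (-1.2 ± 0.22, adjusted p = 0.000582) and the glutamine synthetase gene Glul (-1.03 ± 0.23, adjusted p = 0.0109). In the circadian clock list, 5 of 20 were called below 0 and 6 adjusted over the list alone (camera adjusted p = 0.000105, adjusted p = 0.0761 with an estimated correlation). Bhlhe41 (-3.05 ± 0.55, adjusted p = 0.00054) and Usp2 (-1.94 ± 0.52, adjusted p = 0.0428) were among them. Tff3 (4.74 ± 1.23, adjusted p = 0.0339), Gadd45g (2.59 ± 0.57, adjusted p = 0.00962) and Btg2 (1.83 ± 0.46, adjusted p = 0.0255) were called above 0. So was Mdm2, which encodes the main negative regulator of p53 and was chosen after its values were seen (0.99 ± 0.13, adjusted p = 3.11e-06). In all, 13 of 39 lists passed camera, 2 up and 11 down, and 1 with an estimated correlation.

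Of these interactions, Hamp2 was not called without vehicle atglistatin replicate 14 (-1.72, adjusted p = 0.0814), Btg2 without vehicle control-diet replicate 03 (1.68, adjusted p = 0.0566) or vehicle control-diet replicate 10 (1.54, adjusted p = 0.0631). Tff3 was not called without vehicle control-diet replicate 09 (2.79, adjusted p = 0.264), corticosterone atglistatin replicate 41 (2.93, adjusted p = 0.138), vehicle atglistatin replicate 08 (4.62, adjusted p = 0.0523) or vehicle atglistatin replicate 11 (4.67, adjusted p = 0.0551). Tff3 was at 5.43 without vehicle atglistatin replicate 14. Try5 was not called without any 1 of 26 libraries (-7.76 to -4.14, adjusted p 0.0508 to 0.375), the smallest being that without vehicle atglistatin replicate 06. It was at -9.15 without vehicle control-diet replicate 09 and did not reach the count filter without any 1 of 4 others. Single libraries also ended the calls of Cyp2b10 (33 libraries, -1.63 to -1.39, adjusted p 0.0501 to 0.0985), Cyp4a14 (19 libraries, -1.85 to -1.71, adjusted p 0.0528 to 0.0699), Usp2 (19 libraries, -1.96 to -1.36, adjusted p 0.0501 to 0.144) and Rgs16 (18 libraries, -2.95 to -2.52, adjusted p 0.0503 to 0.091). With limma voom 359 genes passed, but Hamp2, Gadd45g, Btg2, Tff3 and Try5 did not, and Tff3 and Try5 did not with DESeq2. Without the samples labelled diabetic 76 genes passed, 56 above and 20 below 0, of which 62 are among the 181, and without the 6 libraries with Cpa1 above 20 CPM 64 passed, 44 above and 20 below, of which 59 are. In the former setting Hamp2, Cyp4a10, Cyp4a14, Slc37a4, Gadd45g, Btg2, Cyp2b10, Glul, Tff3, Rgs16, Usp2 and Try5 were not called, and in the latter Sqle, Hamp2, Cyp4a14, Slc37a4, Btg2, Cyp2b10, Glul, Tff3, Rgs16 and Usp2.

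Of the 5606 genes changed by corticosterone on the control diet, 66.6% had the opposite sign with atglistatin under corticosterone. The SE was 5.88 over libraries left out in turn. Both comparisons use the corticosterone control-diet libraries, so opposite signs arise by chance. Simulations with a corticosterone effect alone gave 57.3% ± 0.732 (SD of 20). The 66.6% is judged by its SE of 5.88, not this SD. With those 14 libraries split into sets of 7, each used in 1 comparison, the share was 65.6%, and 60.9% with the sets exchanged. Across all 12688 genes, not independent replicates, the fold changes correlated at r = -0.302 (SE 0.103) with a covariance of -0.0756. The same simulations gave r = -0.119 ± 0.0171 and a covariance of -0.0138, and those without any effect r = -0.457 and -0.0134. The split sets gave r = -0.0416 and -0.168 and covariances of -0.0131 and -0.0492. Calls in both comparisons were in opposite directions for 709 genes and in the same direction for 155, and for 316 and 71, and 330 and 79, with the split sets, which share no libraries. Genes higher with corticosterone and lower with atglistatin numbered 435, among them Orm3, Slc34a2 and Fkbp5, and those lower and then higher numbered 274, among them Hmgcs1, Cyp51 and Sqle.

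Within the corticosterone control-diet group, the 9 libraries labelled diabetic were compared with the 5 labelled nondiabetic. No gene passed with edgeR among 12003 tested, the smallest adjusted p was 0.992, and 448 genes had an unadjusted p under 0.05. DESeq2 and limma voom also called 0 genes, with 552 and 1439 at an unadjusted p under 0.05. The glucose-producing G6pc (0.57 ± 0.17, adjusted p = 0.992) and the rate-limiting bile acid gene Cyp7a1 (1.66 ± 0.55, adjusted p = 0.992) did not pass. Camera passed 26 of 38 lists, 18 up and 8 down, and 0 with an estimated correlation. Among them, 0 of 14 gluconeogenesis genes and 0 of 36 PPARα targets passed singly, with 5 and 0 higher adjusted over the list alone (camera adjusted p = 2.72e-06, adjusted p = 0.148 with an estimated correlation for gluconeogenesis, camera adjusted p = 1.52e-09, adjusted p = 0.148 with an estimated correlation for PPARα targets). Insulin was 34.97 ± 7.49 (n = 9) in mice labelled diabetic and 25.7 ± 13.5 (n = 5) in those labelled nondiabetic (exact permutation p = 0.118, adjusted p = 0.133, 2002 arrangements).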

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

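The tests of the clock index, the small RNA index, the samples labelled diabetic, the pancreatic libraries and replicate 41 given here were chosen only after the result was seen, and the counts over other splits of the samples before. In 55 of 520 groups of 5 to 10 samples, a sample's gap to the nearest, as a share of the range, exceeded Dixon's critical value. Chance gives about 1 in 20. The corticosterone atglistatin group was not tested. Values in parentheses are those shares, on log2 CPM for genes. A share of 1 is fixed, as the others all held 0 counts.

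In the vehicle control-diet group (n = 10), replicate 10 was the highest for Apoa4 (0.599) and Dnajb1 (0.726) and the lowest for G0s2 (0.665) and Cyp7a1 (0.631). Replicate 12 was the highest for Tsc22d3 (0.549), Fam107a (0.5195), Mfsd2a (0.479) and Gclc (0.6185). In the vehicle atglistatin group (n = 10), replicate 06 was the highest for Acaca (0.476) and the lowest for Myom3 (0.479). Replicate 13 was the highest for Saa2 (0.4995). Replicate 14 was the highest for Cyp17a1 (0.5145), Tff3 (0.592), Btg2 (0.47), Fmo2 (0.4665) and Mt2 (0.508) and the lowest for Pklr (0.478), G6pc (0.4665), Car3 (0.556), Mup9 (0.484), Mup18 (0.483) and Rhbg (0.472).

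Among the 9 corticosterone control-diet libraries labelled diabetic, replicate 30 was the highest for Cpa1 (0.82), Pnlip (0.798), Cela3b (0.882), Clps (0.842), Rnase1 (0.863), Prss2 (0.869), Cpb1 (0.914), Ctrb1 (0.77), Ctrl (0.847), Try4 (0.88), Try5 (0.8345) and Dnajb1 (0.534). Replicate 34 was the highest for Fam107a (0.6195) and Bhlhe41 (0.514) and the lowest for Snora30 (0.514) and insulin (0.545). Replicate 35 was the highest for fed glucose (0.601). Replicate 45 was the lowest for H2-Aa (0.727), H2-Ab1 (0.6525), Mup17 (0.525) and Car3 (0.516). Replicate 50 was the lowest for Cdkn1a (0.622) and Fgf21 (0.528). Among the 5 labelled nondiabetic, replicate 29 was the highest for Nr1i3 (0.752) and Fmo2 (0.86) and the lowest for Moxd1 (0.822) and Cyp1a2 (0.823). Replicate 36 was the highest for Clps (1) and fed glucose (0.874) and the lowest for Ifit1 (0.714) and Cyp4a10 (0.841). Replicate 49 was the highest for Cpa1 (1) and Cela3b (1).

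For 29 named genes the corticosterone log2 fold change differed between the diets by the interaction test. On the atglistatin diet it was higher, by the values in parentheses, for Tff3 (4.74), Gadd45g (2.59), Btg2 (1.83), Sqle (1.69), Hmgcs1 (1.68), Cyp51 (1.64), Msmo1 (1.57), Fdft1 (1.48), Lss (1.47), Ccng1 (1.01), Mdm2 (0.99), Sc5d (0.95), Mbl2 (0.83) and Gclc (0.73). It was lower, with negative values, for Try5 (-7.61), Bhlhe41 (-3.05), Orm3 (-3.01), Rgs16 (-2.96), Hamp2 (-2.4), Cyp4a10 (-1.95), Usp2 (-1.94), Cyp4a14 (-1.83), Fkbp5 (-1.63), Cyp2b10 (-1.6), Oat (-1.2), Rhbg (-1.18), Glul (-1.03), Acaca (-0.87) and Slc37a4 (-0.8).

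The number of genes called was set beside that of other splits of the same samples, 100 per comparison with the real one included. As many genes as in the real split were called in 1 of 100 splits, the real one, for corticosterone on the control diet (5606 genes, highest other 2950), corticosterone on the atglistatin diet (4652, highest other 902), atglistatin under vehicle (397, highest other 75) and atglistatin under corticosterone (1479, highest other 174). For the interaction 2 of 100 did (181, highest other 188). Chance division of the samples is excluded for the first 4. For the interaction it is so only by the limit of 5 of 100 set before, since 1 other split called more. For the diabetic labels, where edgeR called 0 genes (448 at an unadjusted p under 0.05, and 0 by DESeq2 and limma voom), all 100 splits call as many by construction, so this count says nothing about chance. Of the other splits, 96 called none and the highest called 293.

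Atglistatin calls under vehicle stand beside a clock index that differs between the groups. The median log2 fold change in the called direction was taken with the index as a covariate. For the 14 called CAR and PXR, AHR and NRF2 genes it went from 0.928 (SE 0.12) to 0.7 (SE 0.154). For the other 383 it went from 0.568 (SE 0.034) to 0.385 (SE 0.031). Those lists kept 75.4 percent, and the 373 genes outside these and the circadian list 69.9. Both exceed a limit of 50 but not one of 80, tried later. Calls still ended for all but 14 of the 397 genes, as the folds shrank and the median SE of a gene went from 0.138 to 0.174, and in the circadian list the median went from 1.85 to 0.31. How much of the response collection time carries stays open. The index is made of 2 genes that may follow time only in part and that atglistatin may change. Pancreatic tissue is argued against as the whole cause, since without the 6 libraries the median fold of the 397 genes went from 0.589 (SE 0.033) to 0.553 (SE 0.029), although only 165 of them were still called, with fewer libraries.

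Cholesterol synthesis genes in the interaction had a median of 1.132 (SE 0.104, 25 genes). The median was 1.106 (SE 0.101) with the clock index as a covariate, 1.128 (SE 0.105) with the small RNA index and 1.303 (SE 0.113) without the samples labelled diabetic, with 16, 19 and 19 of 25 called above 0. These values argue against what these indices carry, or the diabetic mice, as the whole cause. A change in sterol synthesis under corticosterone that atglistatin may relieve is a candidate explanation in part. Hmgcs1 also averaged lower with atglistatin under vehicle, which adds to its interaction. Food intake, liver sterol content and group housing were not tested.

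Corticosterone atglistatin replicate 41 stood apart from the 13 others of its group. Its Fkbp5 of 244.4 CPM, against a highest vehicle library of 43.9 CPM, and its mean log2 CPM of 6.87 for the glucocorticoid receptor targets, against at most 5.18, argue against a vehicle liver under a wrong label, although its insulin of 2.19 lay within the 1.19 to 3.46 of vehicle control-diet mice and below the 5.67 or more of its group. Its total count of 13.87, within the 10.83 to 21.18 of its group in units of 10 to the power 6, argues against low depth. It had higher Ccnd1 (350 CPM, others at most 9.77), Tff3 (368, at most 41.9), Cidec (70.4, at most 2.57), Top2a (10.8, at most 0.361) and Mki67 (3.8, at most 0.168), and lower male-biased Hsd3b5 (4.35, others at least 16), Elovl3 (9.12, at least 88.7) and Mup20 (732, at least 1920). What sets it apart stays open, and no biological explanation was tested.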

How the results depend on the processing

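Fits without the libraries with pancreatic transcripts, without replicate 41, without each library in turn for the 5 comparisons of groups, with a clock or small RNA index and with robust estimation were chosen only after the result was seen, and the other settings before. Of the 190 gene results followed, those that kept their direction and side of the threshold numbered 190 with RLE size factors, 187 without a filter on low counts, 176 with the small RNA index, 175 with robust estimation, 165 with DESeq2, 152 with limma voom and 139 with the clock index. They numbered 132 of 139 in fits of the compared groups alone, 141 of 168 without the pancreatic libraries, 100 of 107 without replicate 41 and 78 of 106 without the samples labelled diabetic. Where no cause is given, the cause was not tested.

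Gene counts for corticosterone on the control diet ranged from 4984 to 5994 and on the atglistatin diet from 3948 to 5330, apart from the settings given next and the replicate block. Without the samples labelled diabetic, 3614 genes were called for corticosterone on the control diet, 609 for atglistatin under corticosterone (533 shared with the 1479) and 76 for the interaction (62 shared). Random draws that left out as many libraries gave 3528 to 4647, 269 to 1552 and 41 to 282, with 1, 10 and 8 of 20 draws as low, so fewer libraries alone can give the last 2 counts and seldom the first. The glucose difference for corticosterone on the control diet was 26.2 (permutation adjusted p = 0.112), which follows from leaving out the mice with the highest glucose, and the insulin difference for atglistatin under corticosterone -9.349 (permutation adjusted p = 0.161). With limma voom, 899 genes were called for atglistatin under vehicle (373 shared with the 397) and 359 for the interaction (163 shared). Without the pancreatic libraries these were 207 (165 shared) and 64 (59 shared), where random draws gave 117 to 409 and 61 to 196. With the clock index they were 15 (14 shared) for atglistatin under vehicle and 793 (646 shared) for atglistatin under corticosterone. Leaving out each library in turn gave 5277 to 5732, 4247 to 4710, 277 to 519, 1253 to 1719 and 122 to 237 calls in the 5 comparisons of groups, and 0 for the diabetic labels with edgeR (225 to 870 at an unadjusted p under 0.05).

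The opposition of responses had a correlation of -0.04155 and -0.1676 with split control-diet libraries and -0.4057 without the samples labelled diabetic, and a covariance of -0.01309 and -0.1318 with the first split and without those samples. With an estimated correlation, 2, 1, 3, 2, 1 and 0 gene lists passed camera in place of 16, 11, 15, 13, 13 and 26, since the estimate exceeds the preset 0.01 for most lists.

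Several named genes took the opposite sign. With DESeq2, Dnajb1 was at 0.203 for atglistatin under vehicle and Ccnd1 at -0.048 under corticosterone, where Try5 was at 2.8, Cpb1 4.826, Prss2 3.697, Cela3b 3.75, Try4 3.671, Rnase1 3.506, Ctrb1 2.465, Clps 3.876 and Ctrl 2.391, and Try5 was at 2.17 in the interaction. With limma voom, Dnajb1 was at 0.097, Ccnd1 at -0.005 and Cpb1 at 0.169. Without the samples labelled diabetic, which include the library with the most pancreatic transcripts under corticosterone, Try5 was at 4.453, Cpb1 7.313, Prss2 4.087, Cela3b 5.602, Try4 4.177, Rnase1 5.635, Ctrb1 3.796, Clps 5.24 and Ctrl 2.787 for atglistatin under corticosterone, and Try5 at 1.883 in the interaction. Without the pancreatic libraries, Cpa1 was at 1.826 and Ctrb1 at 2.03 for corticosterone on the atglistatin diet, Dnajb1 at 0.367 for atglistatin under vehicle and Ctrb1 at 3.376 under corticosterone. Without replicate 41, Ccnd1 was at -0.182.

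Some groups share title numbers, but the numbers do not pair the samples. Same-numbered libraries correlated at -0.011, 0.036, -0.117 and -0.05 for 09 to 12 in the vehicle groups and at -0.044 and -0.018 for 13 and 14 in the atglistatin groups, and none correlated best with its own number. With the number as a replicate block, 4 genes were called for atglistatin under vehicle (8 libraries) and 56 for corticosterone on the atglistatin diet (4 libraries). The same libraries without the block gave 0 with edgeR (1484 at an unadjusted p under 0.05) and 300. Of 69 followed results, 14 stayed called in the same direction, or stayed uncalled in either direction, with the block and 20 without it. With and without the block, Cpa1 was at 1.633 and 1.791, Tff3 at -0.415 and -0.331, Clps at 0.967 and 1.352, Cpb1 at 1.706 and 2.135 and Ctrb1 at 1.678 and 1.991, in libraries that leave out vehicle atglistatin replicate 06.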

Other observations

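The tests given here, and the genes apart from Ccng1, Gadd45g, Btg2 and Cdkn1a, were chosen only after the result was seen. Of 13 genes known to be activated by the transcription factor p53, picked without a fixed list and not tested as a set, 9 were higher with atglistatin under corticosterone. Phlda3 rose 17.2-fold (log2 fold change 4.1 ± 0.19, edgeR adjusted p = 2.22e-22), Eda2r 13.7-fold (3.78 ± 0.26, adjusted p = 4.89e-16), Ccng1 2.93-fold (1.55 ± 0.12, adjusted p = 2.03e-14) and Mdm2 2.39-fold (1.26 ± 0.09, adjusted p = 8.44e-16). Phlda3 and Eda2r averaged under 5 CPM, so the size of their folds is uncertain. Plk2 (1.35), Aen (1.29), Trp53inp1 (0.96), Bax (0.94) and Zmat3 (0.83) rose as well, while Gadd45g (0.86, adjusted p = 0.123), Btg2 (0.65, adjusted p = 0.162), Cdkn1a (0.1, adjusted p = 0.841) and Sesn1 (-0.03, adjusted p = 0.924) did not pass. Under vehicle, Eda2r (1.8), Ccng1 (0.54) and Zmat3 (0.4) rose, Gadd45g (-1.73, adjusted p = 0.0171) and Btg2 (-1.18, adjusted p = 0.0442) fell, and the other 8, Phlda3 among them (0.91, adjusted p = 0.0901), did not pass. The difference between the treatments passed for Phlda3 (3.2, adjusted p = 5.54e-07), Gadd45g (2.59), Btg2 (1.83), Eda2r (1.98, adjusted p = 0.0394), Plk2 (1.17), Trp53inp1 (1.11), Aen (1.06), Ccng1 (1.01) and Mdm2 (0.99), and not for Zmat3, Bax, Cdkn1a and Sesn1. No test of a cause was run for these genes.

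The clock index was compared with the number in the sample title within each group, as 4 correlations. In the vehicle atglistatin group (n = 10) r was 0.921 (permutation p = 6e-05, adjusted p = 0.00024) and rho 0.939 (permutation p = 0.00015, adjusted p = 0.0006), and r was 0.905 without the 2 libraries with numbers farthest from the median. In the vehicle control-diet group (n = 10) r was 0.459 (permutation p = 0.181, adjusted p = 0.241), rho 0.442 (permutation p = 0.204, adjusted p = 0.407) and r without those 2 libraries 0.46. The corticosterone control-diet group (n = 14) gave r = 0.513 (permutation p = 0.059, adjusted p = 0.118), rho = 0.244 (permutation p = 0.404, adjusted p = 0.539) and r = 0.338 without 2 libraries. The corticosterone atglistatin group (n = 14) gave r = 0.013 (permutation p = 0.965, adjusted p = 0.965), rho = 0.16 (permutation p = 0.585, adjusted p = 0.585) and r = -0.281 without 2 libraries. If title numbers followed the order of collection, the rho of 0.939 may reflect the hour at which the livers were taken, and these values cannot decide it because the labels give no time.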
